A study of Mus musculus with 20 samples.

How the data were processed

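RNA from the left ventricle of 20 C57BL/6J mice aged 12-15 weeks was measured on Illumina mouse expression BeadChips, 1 array per mouse. Tissue was taken 3 days after coronary artery ligation or sham surgery, with the infarct left out. The 4 groups of 5 mice are male sham, male MI (myocardial infarction by ligation), female sham and female MI. The labels name the group, chip and position of each array. The mice are numbered here within each group in the order of the arrays, and the numbers do not state any pairing. Biotin-labelled cRNA was prepared with an amplification kit for these arrays, per the labels' protocols. The scanner software and the array version are not given in the sources used here.

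The authors deposited a table of bead intensity per probe and array on a linear scale, with no normalisation between arrays and no background subtracted, as its values show. Beside each intensity stands a detection p-value, per the file headers. The authors also deposited a matrix of log2 values whose sorted columns are nearly identical, the mark of quantile normalisation, with no background subtraction visible. Each of its 20 columns correlated best with the array of its own label, with r between 0.997 and 1 on the log2 scale. Its column medians lay between 5.14 and 5.15, its values were not centred, and its direction was that of the intensity. The arrays lie on 4 BeadChips, numbered 1 to 4 here, in positions A to F. Chip 1 carries 3 male sham and 3 male MI arrays. Chip 2 carries 2 male sham, 2 male MI and 2 female sham arrays. Chip 3 carries 2 female sham and 4 female MI arrays, and chip 4 carries 1 array of each female group.

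From the intensity table, values were computed with limma 3.58.1 in R 4.3.3. The function neqc corrected the background by normexp with negative controls inferred from the detection p-values, added an offset of 16, quantile normalised the arrays and took log2. Of 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 were not listed in the platform annotation used here. Updating symbols changed 0 of them. The 18683 probes with a detection p under 0.01 in at least 5 arrays were kept. For each symbol the kept probe with the highest mean over all 20 arrays was tested, which left 12921 genes and unnamed probes, 10278 of them with a symbol. Of the genes with a symbol, 3957 had more than 1 kept probe. Called probes of the same gene went both ways for 5 genes in the male and 21 genes in the female comparison of MI with sham, and for 0 genes in the others. The closest pair of arrays, male MI 1 and male MI 2, differed by a median of 0.148 on the log2 scale over genes, and each array counts as 1 mouse.

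One linear model with a coefficient per group was fitted to all 20 arrays, with 16 residual degrees of freedom and no covariate, because the sources state none. Its contrasts compared MI with sham in males and in females, females with males after sham surgery and after MI, and the response to MI between the sexes (the interaction). A gene was called at an adjusted p under 0.05 by limma's moderated test with Benjamini-Hochberg adjustment, and every adjusted p of a gene below is from that test. Log2 differences are given with their standard error (SE) and 5 mice per group unless another number is stated. A probe whose detection p was not under 0.01 on any array of a group has only a bound there. For such a gene "at least N-fold" sets the bright group's mean against a dim mean in which each array counts at the higher of its lowest detected value and the probe's own value.

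Of 50 gene lists (pathways and cell type markers), the 49 with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were alternatives. The tissue is bulk ventricle, so a marker list describes RNA and never a share of cells. Lists share genes, and cardiac tissue itself expresses many of the markers.

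Genes were named by a fixed rule. It takes, per comparison, the 6 largest rises and the 6 largest falls among called genes with an ordinary symbol whose groups did not overlap. It adds up to 2 genes of each sign with the smallest p from each list described, of which the text gives a part. It always includes 10 genes of cardiac stress and matrix and 4 sex-linked genes measured here. The groups, tests, 50 gene lists and naming rule were fixed before the data were examined. Which of the lists are described, and which of the genes named by the rule are printed, was chosen after their values were seen. Some genes named by the rule are left out because their calls ended when 1 array was left out. The alternatives fixed in advance were other background corrections, scalings and probe filters, every probe tested, the replicate number or the chip as a block, fits to fewer groups or within 1 chip, array weights, an intensity trend, a fold threshold and leaving out each array. Leaving out the 3 arrays in chip position F, and a term for that position, were added after the data had been seen.

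The procedure was tested on simulated arrays with 200 of 12921 genes changed. Their noise was normal, independent between genes and equally wide on every array, with no effect of chip or position. The shares below hold for such arrays and may not hold for the real ones. For MI against sham in males it recovered 44.8% of changes of 0.5 on the log2 scale, 97% of changes of 1 and 100% of changes of 2, and 3.01% of its calls were false. For the sexes after MI the shares were 43.3%, 89.6% and 100%, with 4.32% false. For the interaction they were 7.46%, 73.1% and 100%, with 4% false. Array intensities are not counts.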

Results

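The left ventricle outside the infarct was profiled in 20 mice on day 3 after surgery, with 5 mice in each of the male sham, male MI, female sham and female MI groups. The design asks how the surviving myocardium responds to an infarct and whether that response differs by sex, in a series whose title concerns the better survival of females after infarction. Survival itself was not analysed here. The median raw intensity per array lay between 31.4 and 39.2, and between 15670 and 18388 probes per array were detected, or 34.6% to 40.6% of all probes. The mean number of detected probes was 16569 ± 566 (SD, n = 5) in male sham, 17982 ± 396 in male MI, 17348 ± 604 in female sham and 17363 ± 197 in female MI. The transcripts Xist and the Y-linked Eif2s3y and Kdm5d separated the arrays by sex as labelled, in 20 of 20 arrays. Sex and chip nearly coincide, since only chip 2 carries both sexes, and its female arrays are sham only. The arrays male sham 3, female sham 2 and female MI 4 are each the last array (position F) of their chip. With the group means removed, 577 kept probes lay on average more than 1 log2 unit lower on these 3 arrays than on the others. At any other position 0 probes did so.

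In males, Tnc, which encodes the matrix glycoprotein tenascin-C, rose 13.1-fold (log2 3.71, SE 0.518, adjusted p = 7.09e-05, n = 5 per group). Timp1, an inhibitor of matrix metalloproteinases, rose 8.66-fold (log2 3.11, SE 0.425, adjusted p = 5.55e-05). Lox, the enzyme that cross-links collagen, rose 7.19-fold (log2 2.85, SE 0.315, adjusted p = 1.08e-05). Arg1, the macrophage arginase, rose 10.3-fold (log2 3.36, SE 0.661, adjusted p = 0.00147). Sprr1a, a small proline-rich protein of stressed epithelia and heart muscle, rose 7.77-fold (log2 2.96, SE 0.264, adjusted p = 1.81e-06), and Crct1 was at least 7.57-fold higher after MI (adjusted p = 7.49e-07), being detected on 0 of 5 sham arrays. The falls were smaller. Ano10, of the anoctamin family, fell by 1.56 on the log2 scale (SE 0.175, adjusted p = 1.1e-05) and Retnla, a resistin-like protein of macrophages, fell by 1.33 (SE 0.257, adjusted p = 0.00124). Ttll1, a tubulin-modifying enzyme, fell by 1.21, the lens crystallin gene Cryba4 by 1.20, the circadian repressor Ciart by 1.18 and the kinase gene Wnk2 by 1.13 (adjusted p = 7.44e-05 to 0.00424). By the rule that chose them, each of these 12 genes had every MI array on 1 side of every sham array.

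Proliferation and matrix lists moved together in males. Of 34 measured cell cycle genes 30 rose, 0 fell and 4 did not pass, and 31 rose when adjusted over the list alone (median log2 1.31, camera adjusted p = 3.36e-29, adjusted p = 0.0799 with an estimated correlation). Tyms, thymidylate synthase, rose 3.36-fold (SE 0.191 on the log2 scale, adjusted p = 9.98e-06) and the mitotic kinase gene Aurkb rose 2.65-fold (SE 0.155, adjusted p = 1.06e-05). Of 33 genes of fibrillar collagen and matrix 23 rose, 1 fell and 9 did not pass, and 27 rose and 1 fell when adjusted over the list alone (median 0.87, camera adjusted p = 1.51e-16, adjusted p = 0.0799 with an estimated correlation). Fibronectin (Fn1) rose 5.51-fold (SE 0.28, adjusted p = 1.11e-05), Col1a1 4.08-fold (SE 0.279, adjusted p = 5.94e-05) and Col3a1 3.64-fold (SE 0.361, adjusted p = 0.00131). Of 20 matrix proteases and inhibitors 11 rose and 0 fell, and 13 rose and 1 fell when adjusted over the list alone (median 0.73, camera adjusted p = 7.98e-08, adjusted p = 0.0799 with an estimated correlation), with the aggrecanase gene Adamts4 up 4.19-fold (adjusted p = 7.59e-06). Of 16 myofibroblast genes 9 rose and 0 fell, and 11 rose when adjusted over the list alone (median 0.83, camera adjusted p = 7.83e-08, adjusted p = 0.117 with an estimated correlation). The medians within chip 1 and within chip 2 were 1.47 and 1.19 for the cell cycle, 0.94 and 0.77 for matrix, 0.93 and 0.57 for proteases, and 0.81 and 0.64 for myofibroblast genes. The probe of Col3a1 lay 0.63 log2 units lower in position F (a shift of -0.63), and Col3a1 rose by 1.72 on the log2 scale without those arrays (adjusted p = 0.000889).

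Of 31 macrophage and monocyte genes in males 24 rose and 0 fell, and 28 rose and 1 fell when adjusted over the list alone (median 0.97, camera adjusted p = 1.22e-16, adjusted p = 0.117 with an estimated correlation). Fcer1g, the Fc receptor gamma chain, rose 2.59-fold (SE 0.201, adjusted p = 0.00011) and the mannose receptor gene Mrc1 rose 1.99-fold (SE 0.139, adjusted p = 7.44e-05). Of 11 neutrophil genes 9 rose and 0 fell, and 10 rose when adjusted over the list alone (median 1.12, camera adjusted p = 1.73e-07, adjusted p = 0.16 with an estimated correlation), among them the lectin receptor gene Clec4d at 3.85-fold (adjusted p = 0.000785) and Csf3r, the receptor of the granulocyte colony-stimulating factor, at 1.95-fold (adjusted p = 0.000631). Of 30 chemokines and cytokines 14 rose and 0 fell, and 15 rose when adjusted over the list alone (median 0.53, camera adjusted p = 4.06e-08, adjusted p = 0.137 with an estimated correlation). The monocyte attractant Ccl12 rose 2.83-fold (SE 0.228, adjusted p = 0.00016), and Cxcl10, an interferon-induced chemokine, was at least 1.69-fold higher (adjusted p = 0.000187), with detection on 0 of 5 sham and 5 of 5 MI arrays. Of 29 interferon response genes 6 rose and 0 fell, also 6 when adjusted over the list alone (median 0.23, camera adjusted p = 0.0111, adjusted p = 0.56 with an estimated correlation), and this call ended without male sham 4 (adjusted p = 0.0748). The 5 lymphocyte genes included 2 that rose, 2 also when adjusted over the list alone, and the list was not called (median 0.39, camera adjusted p = 0.0686, adjusted p = 0.349 with an estimated correlation). It passed without male MI 1 (0.0411), without male MI 2 (0.0324) and with fry (0.013). The medians within chips 1 and 2 were 1.05 and 0.84 for macrophages, 1.30 and 1.18 for neutrophils, 0.65 and 0.42 for chemokines, and 0.19 and 0.24 for interferon genes.

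Of 18 ventricular stress genes in males 3 rose and 0 fell, and 4 rose when adjusted over the list alone (median 0.22, camera adjusted p = 0.0441, adjusted p = 0.464 with an estimated correlation). Nppa, atrial natriuretic peptide, rose 1.80-fold (SE 0.16, adjusted p = 0.0011) and the LIM protein gene Fhl1 rose 1.72-fold (SE 0.176, adjusted p = 0.00394). Nppa had a log2 difference of 0.50 and an adjusted p of 0.0634 with 75th percentile scaling, and its values in male MI (13.53 to 13.83) lie near the highest of the scale (13.99). Ankrd1, a nuclear stress cofactor, rose 1.41-fold with an adjusted p of 0.049, and leaving out any of 14 arrays singly ended that call, with a highest adjusted p of 0.119 without male sham 2. With every kept probe tested, a dimmer Ankrd1 probe had a log2 difference of 0.99 (adjusted p = 0.185), against 0.49 for the chosen probe. Brain natriuretic peptide (Nppb, log2 0.58, SE 0.278, adjusted p = 0.153), the myosin genes Myh6 (log2 0.00, SE 0.0863, adjusted p = 0.998) and Myh7 (log2 0.56, SE 0.296, adjusted p = 0.2), skeletal actin Acta1 (log2 -0.12, SE 0.314, adjusted p = 0.826) and the calcium pump gene Atp2a2 (log2 -0.05, SE 0.0851, adjusted p = 0.711) were not called, though Atp2a2 passed with 75th percentile scaling (log2 -0.38, adjusted p = 0.0289). The probes of Myh6 and Atp2a2 also lie near the top of the scale, and their dimmer probes did not pass (Myh6 0.34, adjusted p = 0.782, and Atp2a2 -0.15, adjusted p = 0.558, with every kept probe tested). Without the position F arrays Nppb had a log2 difference of 0.77 (adjusted p = 0.0399). Of 20 contractile genes 1 rose and 2 fell, the same numbers when adjusted over the list alone (median -0.03, camera adjusted p = 0.723, but -0.37 and 0.00681 with 75th percentile scaling), and the tropomyosin gene Tpm1 rose 1.67-fold (adjusted p = 0.00533). Of 15 calcium handling genes 3 fell and 0 rose, and 4 fell when adjusted over the list alone (median -0.27, camera adjusted p = 0.129, and 0.0106 with fry), among them Hrc, a calcium-binding protein of the sarcoplasmic reticulum, which fell by 0.64 on the log2 scale (SE 0.133, adjusted p = 0.00238). Phospholamban (Pln) had a log2 difference of 0.85 (SE 1.01, adjusted p = 0.604), and its probe shifted by -4.38 in position F.

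Energy metabolism and ion channel lists in males lay below sham, by an amount that depended on the scaling. Of 40 oxidative phosphorylation genes 7 fell and 0 rose, 7 also when adjusted over the list alone (median -0.17, camera adjusted p = 0.0169, adjusted p = 0.458 with an estimated correlation), for example Ndufs8 of complex I, which fell by 0.45 on the log2 scale (SE 0.109, adjusted p = 0.00683). Of 31 fatty acid oxidation genes 5 fell and 0 rose, 5 also when adjusted over the list alone (median -0.17, camera adjusted p = 0.0332, adjusted p = 0.508 with an estimated correlation). The dehydrogenase gene Acads fell by 0.60 (SE 0.159, adjusted p = 0.0128) and the electron carrier gene Etfb by 0.37 (SE 0.0912, adjusted p = 0.00706). Of 17 genes of branched chain amino acid breakdown 2 fell and 0 rose, 2 also when adjusted over the list alone (median -0.23, camera adjusted p = 0.0332, adjusted p = 0.425 with an estimated correlation), with Mcee down by a log2 difference of -0.58 (adjusted p = 0.00329). Of 20 potassium and sodium channel genes 6 fell and 0 rose, and 7 fell when adjusted over the list alone (median -0.25, camera adjusted p = 0.044, adjusted p = 0.458 with an estimated correlation). The potassium channel genes Kcnv2 and Kcnj8 fell by 0.91 (SE 0.222, adjusted p = 0.00706) and by 0.55 (SE 0.139, adjusted p = 0.00951). Of 19 citric acid cycle genes 1 fell and 0 rose, and 0 when adjusted over the list alone (median -0.17, camera adjusted p = 0.129). The medians within chips 1 and 2 were -0.17 and -0.14 for oxidative phosphorylation, -0.19 and -0.16 for fatty acid oxidation, -0.20 and -0.29 for amino acid breakdown, and -0.36 and -0.30 for channels. With 75th percentile scaling the medians were -0.45 for oxidative phosphorylation, -0.39 for fatty acid oxidation, -0.44 for amino acid breakdown, -0.30 for channels and -0.41 for the citric acid cycle.

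The weaker male list calls rested on single arrays. Without male MI 3 the camera adjusted p was 0.0807 for ventricular stress, 0.193 for fatty acid oxidation, 0.0807 for branched chain amino acid breakdown and 0.142 for potassium and sodium channels. Without male sham 4 the 4 values were 0.118, 0.0973, 0.118 and 0.0772. The ventricular stress call also ended without male sham 1 (0.0533), male MI 1 (0.0591), male MI 2 (0.0574) and female MI 3 (0.055). With 75th percentile scaling its median was 0.000488, so that the rise vanished, and its camera adjusted p was 0.28. The fatty acid oxidation call also ended without male sham 2 (0.0586) and male sham 5 (0.0551). The channel call also ended without male sham 2 (0.052), male sham 5 (0.0647), male MI 5 (0.0548) and female sham 3 (0.0515). The citric acid cycle list, not called above, passed under 5 other settings and without 1 array. They were 75th percentile scaling (camera adjusted p = 0.0117), no filter on dim probes (0.0329), array weights (0.0282), leaving out the position F arrays (0.0104), a term for that position (0.0212) and leaving out male sham 3 (0.0264).

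In total limma called 2373 of 12921 genes in males, 1263 up and 1110 down, with 291 up and 17 down by at least 2-fold. Groups did not overlap for 18.1% of genes, against 0.794% by chance. With the chip as a block 2510 genes were called, within chip 1 alone 2160 and within chip 2 alone, with 2 arrays per group, 624 (562 up and 62 down). With 75th percentile scaling 998 rose and 2047 fell, so that 32.8% of calls were up against 53.2% with quantile normalisation. The median over all genes was then -0.13, against -0.04 with quantile normalisation. Array weights gave 4150 genes, and leaving out the position F arrays 2557.

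In females 5 of the 6 leading rises and 2 of the 6 leading falls were those of males. Tnc rose 14.5-fold (log2 3.86, SE 0.518, adjusted p = 1.35e-05, n = 5 per group), Sprr1a 11.7-fold (log2 3.55, SE 0.264, adjusted p = 1.26e-07), Arg1 10.2-fold (log2 3.35, SE 0.661, adjusted p = 0.000637) and Timp1 9.85-fold (log2 3.30, SE 0.425, adjusted p = 8.54e-06). Cthrc1, a secreted protein of activated fibroblasts, rose 10.7-fold (log2 3.42, SE 0.324, adjusted p = 3.97e-07), and Crct1 was at least 8.64-fold higher (adjusted p = 1.31e-07). Ano10 fell by 1.97 on the log2 scale (SE 0.175, adjusted p = 2.05e-07) and Kcnv2, a modifier subunit of potassium channels, fell by 1.88 (SE 0.222, adjusted p = 3.85e-06). The methyltransferase gene Inmt fell by 1.67, the muscle gene Ky by 1.57, Ttll1 by 1.53 and the GTPase regulator gene Tbc1d10c by 1.41 (adjusted p = 2.23e-06 to 0.00011). Of the 12 leading genes of males, Ciart was not called in females (log2 -0.33, adjusted p = 0.372, interaction adjusted p = 0.571). The plot of 6 genes by array shows the spread behind these means.

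**Figure D1:**
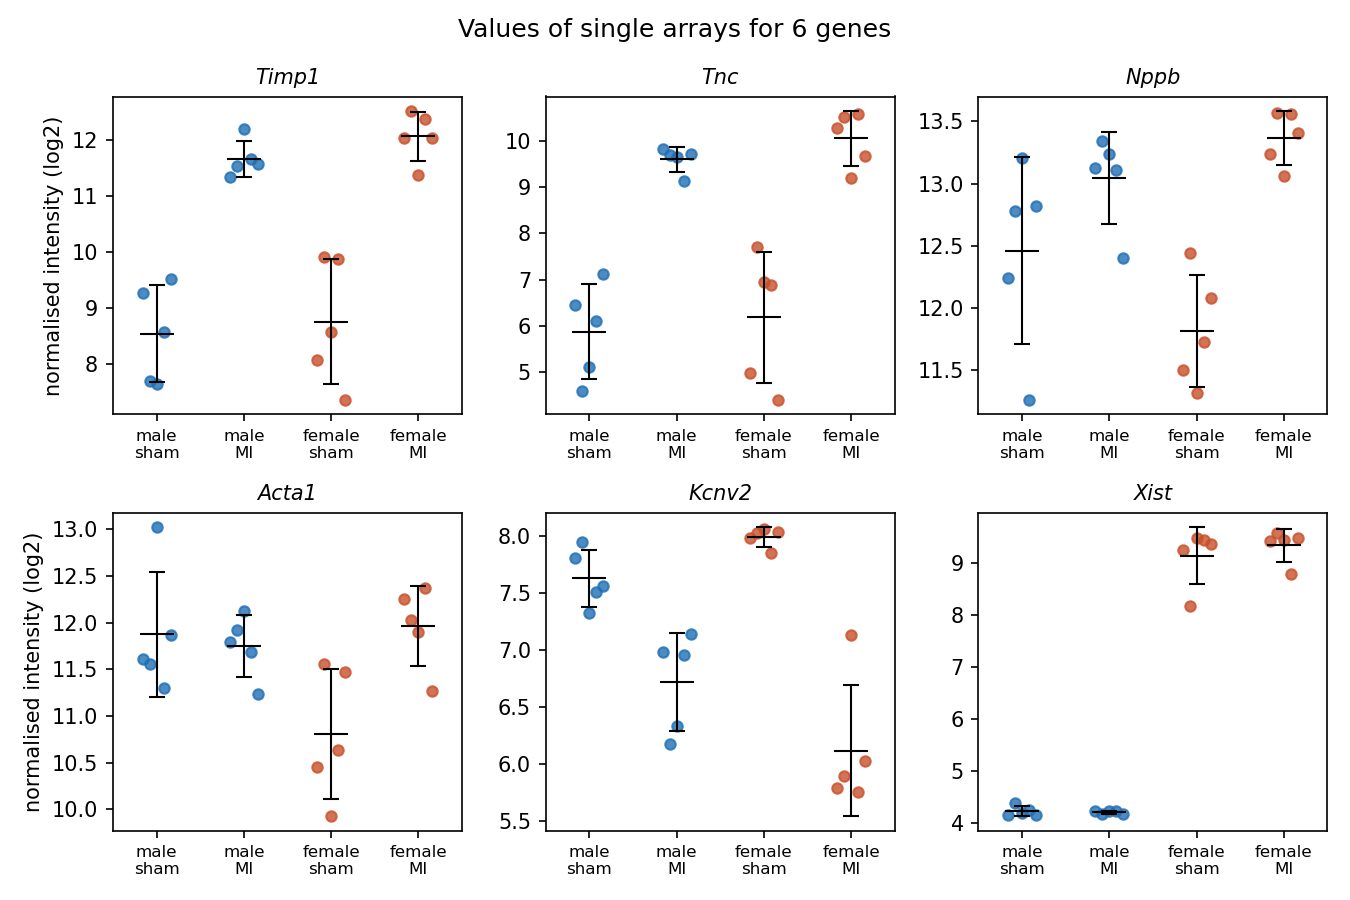
Normalised log2 intensity of 6 genes on each of the 20 arrays, with the mean and SD (n = 5) of each group as bars. Tnc and Timp1 were higher in MI than in sham in both sexes, Kcnv2 was lower, Nppb and Acta1 passed only the test in females (interaction adjusted p = 0.554 for both), and Xist separated the sexes.

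Matrix and proliferation lists in females included more called members. Of 34 cell cycle genes 31 rose and 1 fell, and 33 rose and 1 fell when adjusted over the list alone (median log2 1.56, camera adjusted p = 4.76e-23, adjusted p = 0.116 with an estimated correlation). Tyms rose 4.75-fold (SE 0.191, adjusted p = 1.53e-07) and Aurkb 3.47-fold (SE 0.155, adjusted p = 1.76e-07). Of 33 matrix genes 27 rose and 2 fell, and 28 rose and 2 fell when adjusted over the list alone (median 1.19, camera adjusted p = 1.55e-15, adjusted p = 0.116 with an estimated correlation). The collagen gene Col8a1 rose 6.02-fold (SE 0.232, adjusted p = 2.05e-07), the microfibril gene Mfap5 3.39-fold (SE 0.151, adjusted p = 1.72e-07), Col1a1 4.08-fold (SE 0.279, adjusted p = 1.77e-05) and Col3a1 3.57-fold (SE 0.361, adjusted p = 0.000613), while the proteoglycan gene Fmod fell by 0.41 (SE 0.121, adjusted p = 0.0121). Of 20 proteases and inhibitors 14 rose and 0 fell, 14 also when adjusted over the list alone (median 1.08, camera adjusted p = 2.2e-08, adjusted p = 0.116 with an estimated correlation), with Adamts4 up 5.22-fold and the macrophage elastase gene Mmp12 up 3.79-fold (adjusted p = 2.03e-07 and 3.71e-06). Of 16 myofibroblast genes 13 rose and 0 fell, 13 also when adjusted over the list alone (median 0.97, camera adjusted p = 1.37e-08, adjusted p = 0.116 with an estimated correlation). The 4 medians were 1.53, 1.15, 1.13 and 1.04 with the chip as a block, and within chip 3 they were 1.5, 1.11, 1.03 and 1.06.

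Leukocyte lists in females rose as well. Of 31 macrophage and monocyte genes 29 rose and 0 fell, 29 also when adjusted over the list alone (median 1.21, camera adjusted p = 7.83e-16, adjusted p = 0.123 with an estimated correlation), with the monocyte gene Ms4a7 up 4.59-fold (SE 0.274, adjusted p = 6.35e-06) and Fcer1g up 3.37-fold (SE 0.201, adjusted p = 2.84e-06). Of 11 neutrophil genes 10 rose and 0 fell, 10 also when adjusted over the list alone (median 1.13, camera adjusted p = 2.48e-06, adjusted p = 0.194 with an estimated correlation), with Clec4d up 5.55-fold (adjusted p = 2.76e-05). Of 30 chemokines and cytokines 18 rose and 0 fell, and 19 rose and 1 fell when adjusted over the list alone (median 0.80, camera adjusted p = 3.87e-08, adjusted p = 0.137 with an estimated correlation). Cxcl10 was at least 3.56-fold higher (adjusted p = 2.81e-07) and the macrophage inflammatory protein gene Ccl3 at least 2.69-fold higher (adjusted p = 2.78e-06). Of 29 interferon response genes 16 rose and 0 fell, and 21 rose when adjusted over the list alone (median 0.60, camera adjusted p = 7.39e-08, adjusted p = 0.211 with an estimated correlation), for example Oasl2 at 1.93-fold (SE 0.138, adjusted p = 3.14e-05). Of 5 lymphocyte genes 3 rose and 0 fell, and 4 rose when adjusted over the list alone (median 0.60, camera adjusted p = 0.0103, adjusted p = 0.149 with an estimated correlation), among them the surface protein gene Thy1 at 2.47-fold (adjusted p = 1.31e-05) and the chemokine gene Ccl5 at 2.00-fold (adjusted p = 0.00054). Thy1 is also in the fibroblast list and Ccl5 in the chemokine list, so neither is specific to lymphocytes. The 5 medians in this order were 1.07, 1.24, 0.85, 0.58 and 0.52 with the chip as a block, and within chip 3 they were 1.03, 1.00, 0.70, 0.59 and 0.49.

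Of 18 ventricular stress genes in females 9 rose and 0 fell, 9 also when adjusted over the list alone (median 0.50, camera adjusted p = 0.000946, adjusted p = 0.194 with an estimated correlation). Nppb rose 2.93-fold (SE 0.278, adjusted p = 0.000255), Acta1 2.23-fold (SE 0.314, adjusted p = 0.00759), Nppa 1.85-fold (SE 0.16, adjusted p = 0.000269) and Ankrd1 1.53-fold (SE 0.171, adjusted p = 0.00897, and 0.0534 with the chip as a block). The Nppa probe is the one that lay near the top of the scale in male MI. A dimmer Ankrd1 probe rose by 1.55 on the log2 scale with every kept probe tested (adjusted p = 0.0234), against 0.61 for the chosen probe. Myh7 had a log2 difference of -0.55 (SE 0.296, adjusted p = 0.161), and -0.94 with the chip as a block (adjusted p = 0.0319). Myh6 (log2 -0.08, SE 0.0863, adjusted p = 0.517) and Atp2a2 (log2 0.04, SE 0.0851, adjusted p = 0.736) were not called. Their dimmer probes did not pass either, with every kept probe tested (Myh6 -1.31, adjusted p = 0.161, and Atp2a2 -0.37, adjusted p = 0.0726). The probe of Acta1 lay 0.90 log2 units higher in position F, and Acta1 rose by 1.24 without those arrays (adjusted p = 0.00126). Of 20 contractile genes 1 rose and 5 fell, the same numbers when adjusted over the list alone (median -0.08, camera adjusted p = 0.267). That list passed with 75th percentile scaling (median -0.27, adjusted p = 0.0269), with every kept probe tested (0.0106) and with fry (0.0048). Tpm1 rose 2.03-fold (adjusted p = 0.000145), while Myom2, of the sarcomeric M-band, fell by 0.75 (SE 0.158, adjusted p = 0.00108). Of 15 calcium handling genes 3 fell and 0 rose, 3 also when adjusted over the list alone (median -0.24, camera adjusted p = 0.106, but 0.00142 with fry and 0.0482 without the position F arrays), and Hrc fell by 0.79 (SE 0.133, adjusted p = 0.000131).

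Of 31 fatty acid oxidation genes in females 20 fell and 0 rose, and 21 fell when adjusted over the list alone (median -0.50, camera adjusted p = 8.76e-07, adjusted p = 0.137 with an estimated correlation). The thioesterase gene Acot1 fell by 1.27 on the log2 scale (SE 0.239, adjusted p = 0.00041) and Etfb by 0.49 (SE 0.0912, adjusted p = 0.000339). Of 17 genes of branched chain amino acid breakdown 13 fell and 1 rose, the same numbers when adjusted over the list alone (median -0.59, camera adjusted p = 2.61e-05, adjusted p = 0.123 with an estimated correlation). Dbt, a subunit of the branched chain ketoacid dehydrogenase, fell by 0.90 (SE 0.132, adjusted p = 3.31e-05) and Ivd by 0.69 (SE 0.108, adjusted p = 6.61e-05), while Auh rose 1.68-fold (SE 0.14, adjusted p = 0.000375). Of 19 citric acid cycle genes 9 fell and 0 rose, and 10 fell when adjusted over the list alone (median -0.42, camera adjusted p = 0.000297, adjusted p = 0.211 with an estimated correlation), with Dlat of the pyruvate dehydrogenase complex down by a log2 difference of -0.79 and Suclg2 by -0.75 (adjusted p = 7.26e-05 and 0.000108). Of 40 oxidative phosphorylation genes 13 fell and 0 rose, and 15 fell when adjusted over the list alone (median -0.25, camera adjusted p = 0.000188, adjusted p = 0.194 with an estimated correlation), with Sdhb down by -0.50 and Ndufa9 by -0.43 (adjusted p = 0.00116 and 0.00176). Of 20 potassium and sodium channel genes 10 fell and 0 rose, and 11 fell when adjusted over the list alone (median -0.52, camera adjusted p = 0.000103, adjusted p = 0.134 with an estimated correlation). Abcc9, the regulatory subunit of the ATP-sensitive potassium channel, fell by 1.06 (SE 0.159, adjusted p = 4.2e-05). Blocking on the chip gave medians of -0.53, -0.62, -0.52, -0.24 and -0.52, and within chip 3 they were -0.55, -0.68, -0.51, -0.20 and -0.54.

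**Figure D2:**
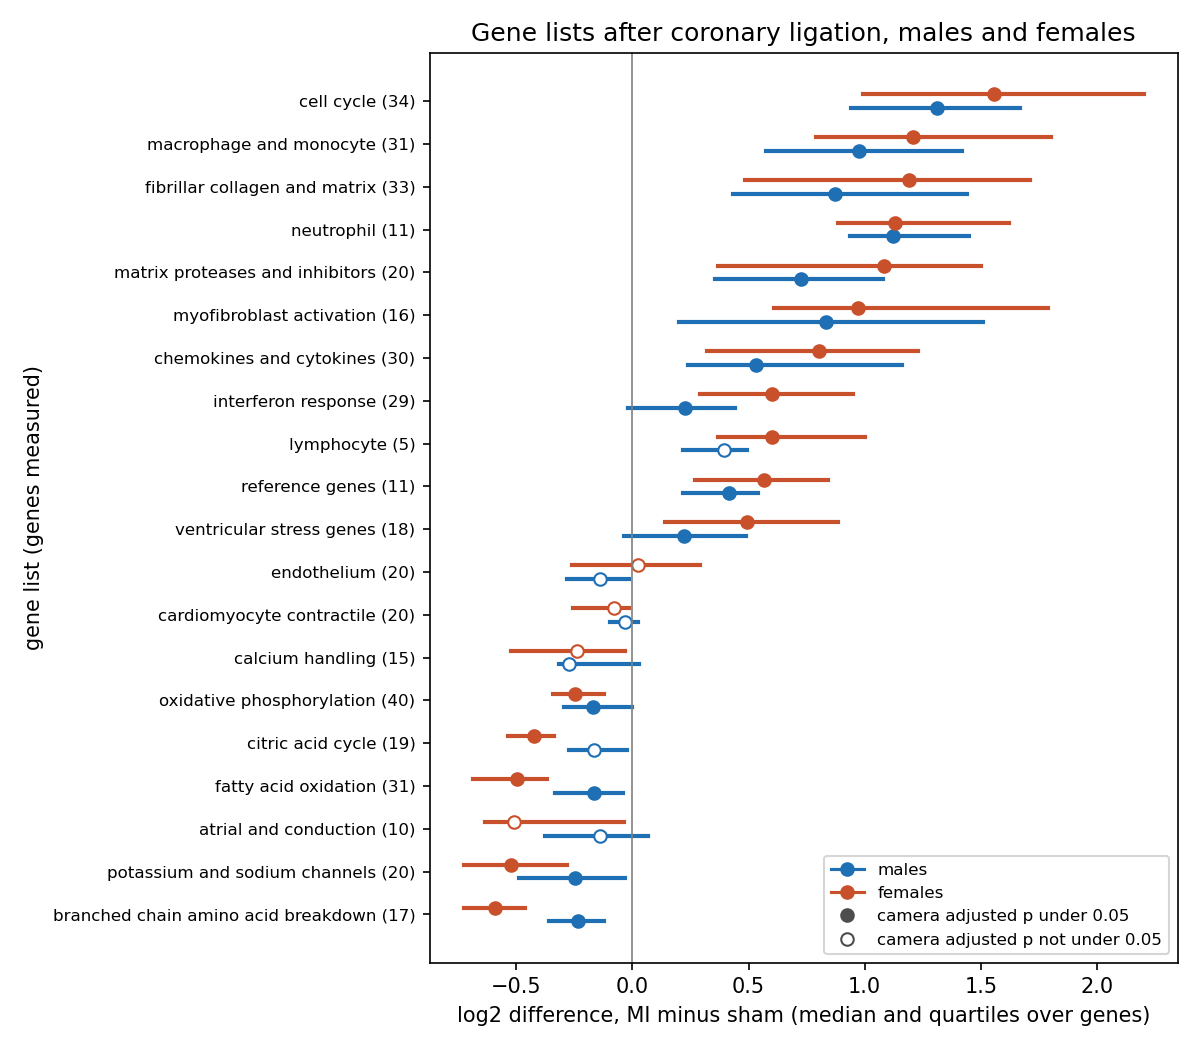
Median log2 difference of MI minus sham (point) and quartiles over the measured genes (line) for 20 gene lists in males and females. Filled points passed camera at the preset correlation. With an estimated correlation 0 lists passed, and fry called 21 of the 49 tested lists in males and 35 in females. Cell cycle, leukocyte and matrix lists lie to the right in both sexes and metabolic lists to the left, and the female endothelium median changes sign with the scaling (0.03 against -0.01 with 75th percentile scaling).

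Endothelial genes as a list were not called in either sex. Of 20 measured, 0 rose and 0 fell in males (median -0.14, and -0.28 with 75th percentile scaling, camera adjusted p = 0.273) and 1 rose and 1 fell in females (median 0.03, and -0.01 with 75th percentile scaling, camera adjusted p = 0.798). Genes often used as references did move, and of 11 measured 4 rose in males and 6 in females, 6 and 7 when adjusted over the list alone (medians 0.42 and 0.57, camera adjusted p = 0.00292 and 0.000549, adjusted p = 0.0799 and 0.116 with an estimated correlation). With 75th percentile scaling the medians were 0.19 and 0.46. Beta-actin (Actb) rose 1.91-fold in males (SE 0.176, adjusted p = 0.00105) and 2.16-fold in females (SE 0.176, adjusted p = 7.3e-05), and the ribosomal gene Rplp0 rose 2.07-fold in females (SE 0.166, adjusted p = 7.26e-05). Actb is 1 of the genes whose called probes went both ways. With every kept probe tested, 2 dimmer Actb probes fell, with log2 differences of -2.70 and -2.63 in males (adjusted p = 0.00145 and 0.00157) and of -2.33 and -2.40 in females (adjusted p = 0.00202 and 0.00142).

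An offset of 50 in place of 16 lowered some list medians by more than 1.5 times without ending their calls. In males they were then 0.84 for the cell cycle, 0.68 for neutrophils, 0.46 for proteases and 0.26 for chemokines and cytokines, and in females 0.66 for neutrophils, 0.51 for chemokines and cytokines and 0.27 for lymphocytes. The uncalled male medians were 0.18 for lymphocytes and -0.16 for calcium handling. For the Y-linked list the medians between the sexes were -0.92 after sham surgery and -0.97 after MI. Medians of lists given further below also shrank. They were 0.36 in males and 0.44 in females for leukocyte adhesion and entry, and 0.208 and 0.245 for acute phase and complement. Between the sexes after sham surgery they were 0.0949 for the cell cycle and -0.112 for antigen presentation.

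In females limma called 4231 genes, 2126 up and 2105 down, with 560 up and 81 down by at least 2-fold. Groups did not overlap for 14.9% of genes, against 0.794% by chance. With the chip as a block 3378 genes were called (1958 up and 1420 down), and within chip 3 alone, with 2 sham and 4 MI arrays, 946 (676 up and 270 down). Chip 4 carries 1 array of each female group and gives no test. Without the position F arrays 4174 genes were called.

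Of the genes called in either sex, 1835 of 4769 were called in both. Both sexes called 1125 genes up, against 208 for independent lists, and 710 down, against 181, and 0 genes were called in opposite directions. The 2 comparisons share each gene's variance from the same fit, so genes with a small variance are called more easily in both. The numbers for independent lists are therefore not the overlap to be had without a shared response. Over all genes, which are not independent replicates, the log2 differences of males and females correlated with r = 0.82 and rho = 0.70. Between chip 1 males and chip 3 females r was 0.52, and between chip 2 males and chip 3 females 0.78. Of these shared genes 1326 (72.3%) had the larger difference in females, with a median absolute log2 difference of 0.73 against 0.60 in males. Of 2396 genes called only in females 91.0% had the same sign in males, and of 538 called only in males 93.1% had the same sign in females. Among the genes called in 1 sex only, 0 passed the test of the interaction.

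That test, of whether the response to MI differed by sex, called 0 of 12921 genes, with a smallest adjusted p of 0.554. At an unadjusted p under 0.05 there were 1091 genes, against 646.1 by chance. Array weights called 31 genes and every other setting 0. Among the named genes the female response exceeded the male one for Acta1 (log2 1.28, SE 0.444), the antiviral gene Rsad2 (1.09, SE 0.318), Nppb (0.97, SE 0.393) and elastin (Eln, 0.95, SE 0.291). It lay below for Myh7 (-1.11, SE 0.419), Ky (-0.99, SE 0.339), the fatty acid oxidation gene Hadh (-0.99, SE 0.336) and Kcnv2 (-0.96, SE 0.314), and the adjusted p was 0.554 for all of these. Fos (-1.11, SE 0.816, adjusted p = 0.686) and Pln (-1.09, SE 1.43, adjusted p = 0.833) had wide errors. No size is given for Gdf3 and Cxcl10 (adjusted p = 0.554 for both), which were detected on 0 of 5 male sham arrays, so that their values there lie at background. With array weights Cxcl10 had an adjusted p of 0.0488, within a range of 0.0488 to 0.819 over all settings and left-out arrays.

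Gene lists differed by sex only under the preset correlation. The female response was higher for the interferon list (median log2 0.34, camera adjusted p = 2.52e-06) and lower for fatty acid oxidation (-0.26, 2.55e-06), branched chain amino acid breakdown (-0.33, 0.000142) and potassium and sodium channels (-0.34, 0.00129). Their adjusted p was 0.565 with an estimated correlation in each case and 0.36 with fry. Of their members 0 passed over all genes, and 4 of branched chain amino acid breakdown passed downward when adjusted over the list alone, against 0 of the 3 other lists. Pccb, a subunit of propionyl-CoA carboxylase, and Ivd, isovaleryl-CoA dehydrogenase, had log2 differences of -0.60 (SE 0.198) and -0.46 (SE 0.153). Blocking on the chip gave medians of 0.29, -0.32, -0.45 and -0.19, without the position F arrays 0.20, -0.21, -0.36 and -0.31, and with 75th percentile scaling 0.35, -0.13, -0.19 and -0.24. The matrix list (median 0.23, camera adjusted p = 0.0123, adjusted p = 0.615 with an estimated correlation) lost its call with the chip as a block (0.219) and on leaving out singly male sham 4 (0.0527), male sham 5 (0.0695), male MI 4 (0.0537), female MI 1 (0.0554), female MI 4 (0.0553) or female sham 5 (0.135). No chip carries both sexes with both surgeries, so no value within a chip can be given.

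Between females and males after sham surgery, Xist, the RNA that silences an X chromosome, was at least 18.7-fold higher in females (adjusted p = 2.61e-13, n = 5 per group). The Y-linked Eif2s3y was at least 12.7-fold higher in males (adjusted p = 3.93e-08) and Kdm5d at least 2.35-fold (adjusted p = 2.5e-08), and Uty was lower in females by a log2 difference of -0.90 (SE 0.121, adjusted p = 0.000504). Kdm6a, which escapes X inactivation, was 2.06-fold higher in females (SE 0.101, adjusted p = 3.09e-06). Of other genes, the complement gene C7 was lower in females (log2 -1.04, SE 0.118, adjusted p = 3.9e-05). Of 3 Y-linked genes 3 were lower (camera adjusted p = 3.76e-15, and 0.00021 with an estimated correlation), 3 also when adjusted over the list alone. Of 6 genes of X inactivation and escape 3 were higher (5.69e-13 and 0.000283), and 4 when adjusted over the list alone. Within chip 2, on 2 arrays per sex, the medians of these lists were -1.88 and 0.52, and with the chip as a block -1.85 and 0.63.

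In all 14 genes differed after sham surgery, 7 higher and 7 lower in females, 6 of them in the sex lists. Groups did not overlap for 1.64% of genes, against 0.794% by chance. At an unadjusted p under 0.05 there were 1635 genes, against 646.1 by chance. With the chip as a block 7 genes were called, and within chip 2 alone 1. The remaining named genes were the matrix genes Col14a1 (log2 0.80, SE 0.14, adjusted p = 0.015) and Lum (1.04, SE 0.196, 0.0314), the X-linked Pbdc1 (0.71, SE 0.128, 0.0181), the intermediate filament gene Synm (0.67, SE 0.13, 0.0405), Urah (-0.72, SE 0.125, 0.0137) and Fah, of tyrosine breakdown (-0.69, SE 0.135, 0.0413). With the chip as a block these 6 had adjusted p values of 0.0534 (Fah) to 0.651 (Synm). The calls of Col14a1, Pbdc1, Lum, Synm and Fah each ended without male sham 1, without male sham 2 and without female sham 4, with values of 0.0535 to 0.159. In all, leaving out singly any of 4, 3, 7, 12 and 13 arrays ended them. The total was 9 without male sham 1 or female sham 4, 26 without female sham 2 and 45 without male sham 4. Without the position F arrays it was 20, and 39 with a term for that position.

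Some lists of other genes leaned towards females in sham hearts without called members. Immediate early genes had a median of 0.37 (0 of 19 called, 0 when adjusted over the list alone, camera adjusted p = 0.000112, adjusted p = 0.576 with an estimated correlation), led by Fos (log2 1.73, SE 0.577, adjusted p = 0.222), whose probe shifted by -0.98 in position F. Adipocyte genes had a median of 0.34, with 0 of 8 called and 3 when adjusted over the list alone (camera adjusted p = 0.0479, adjusted p = 0.576 with an estimated correlation), led by the carbonic anhydrase gene Car3 (log2 1.36, SE 0.358, adjusted p = 0.153). The adipocyte median turned to -0.08 with a filter for detection on all 20 arrays (adjusted p = 0.981), and was 0.19 with an offset of 50 (adjusted p = 0.0649). Leaving out any of 13 arrays singly ended the call, with a highest adjusted p of 0.153 without male sham 4. The medians within chip 2 were 0.25 and 0.15, and with the chip as a block 0.34 and 0.24. The 10 cardiac stress and matrix genes named by the rule had adjusted p values of 0.189 (Acta1) to 0.993 (Nppa).

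Between females and males after MI, 18 genes differed, 9 higher and 9 lower in females. Xist was at least 24.5-fold higher in females (adjusted p = 1.09e-13, n = 5 per group), and Eif2s3y at least 17.2-fold and Kdm5d at least 2.49-fold higher in males (adjusted p = 7.1e-09 for both). C7 was at least 1.53-fold higher in males (adjusted p = 0.000239), detected on 5 of 5 male and 0 of 5 female arrays. Gdf3, a growth factor of the TGF-beta family, was 2.53-fold higher in females (SE 0.222, adjusted p = 0.00702), Pbdc1 1.92-fold (SE 0.128, adjusted p = 0.000691) and the chaperone gene Fkbp14 1.60-fold (SE 0.0945, adjusted p = 0.000847). The glucocorticoid-activating enzyme gene Hsd11b1 was lower in females (log2 -0.98, SE 0.163, adjusted p = 0.00702). Mmgt2 was 1.54-fold higher (SE 0.101, adjusted p = 0.00702). Uty had a log2 difference of -0.53 (SE 0.121, adjusted p = 0.0834, and 0.0235 without female MI 3). After sham surgery, Hsd11b1 (log2 -0.68, adjusted p = 0.131) and Mmgt2 (0.46, 0.0796) lay in the same direction without a call. Fkbp14 (0.18, 0.429) and Gdf3 (adjusted p = 0.964) were not called there either.

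Other calls of that comparison were near the threshold. The histone methyltransferase gene Ezh2 (log2 0.75, SE 0.133, adjusted p = 0.0139) lost its call without male MI 1 (0.0563), female MI 1 (0.0623), female MI 2 (0.0533) or female MI 4 (0.0654). The chemokine gene Cxcl14 (-1.01, SE 0.193, 0.0299) and Eepd1 (-0.65, SE 0.13, 0.0475) lost theirs on leaving out any of 7 and 15 arrays, with highest values of 0.105 without male MI 4 and 0.208 without female MI 1. After sham surgery Ezh2 (log2 0.53, adjusted p = 0.138) and Cxcl14 (-0.89, 0.0796) lay in the same direction without a call, and Eepd1 (0.16, 0.633) in the other. No chip carries both MI groups. With the chip as a block, an estimate that runs through the sham arrays, 4 genes were called, and Gdf3, Pbdc1, Mmgt2 and Hsd11b1 had an adjusted p of 0.314, and C7 and Fkbp14 of 0.0934. The count was 11 without female MI 2 or female MI 4, 635 without female MI 3, and 1981 with array weights, which gave female MI 3, 4 and 5 weights of 0.517, 0.457 and 0.548. At an unadjusted p under 0.05 there were 1922 genes, against 646.1 by chance, and groups did not overlap for 3.07% of genes, against 0.794% by chance. With sham surgery this comparison shared 3 genes up and 4 down.

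After MI, of 3 Y-linked genes 2 were lower, 3 when adjusted over the list alone (camera adjusted p = 2.54e-12, and 0.000701 with an estimated correlation), and of 6 genes of X inactivation and escape 3 were higher, 3 also when adjusted over the list alone (9.76e-10 and 0.00168). The interferon list was higher in females with a median of 0.37, 0 of 29 genes called and 13 when adjusted over the list alone (camera adjusted p = 3.39e-10, adjusted p = 0.243 with an estimated correlation). Its members Cxcl10 (log2 0.96, SE 0.201, adjusted p = 0.0617) and Usp18 (0.82, SE 0.237, 0.152) were called without female MI 3 (0.0111 and 0.0313), and Cxcl10 also without female MI 5 (0.00169). The matrix list had a median of 0.41, 0 of 33 called and 10 when adjusted over the list alone (camera adjusted p = 5.55e-10, adjusted p = 0.243 with an estimated correlation). Branched chain amino acid breakdown had a median of -0.30, 0 of 17 called and 5 lower when adjusted over the list alone (camera adjusted p = 1.62e-05, adjusted p = 0.212 with an estimated correlation), led by Dbt (-0.56, SE 0.132, adjusted p = 0.098, and 0.0111 without female MI 3). Blocking on the chip gave medians of 0.26, 0.41 and -0.38, and the first and second lists had a camera adjusted p of 0.0939. The 10 cardiac stress and matrix genes had adjusted p values of 0.273 (Myh7) to 0.997 (Ankrd1).

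**Figure D3:**
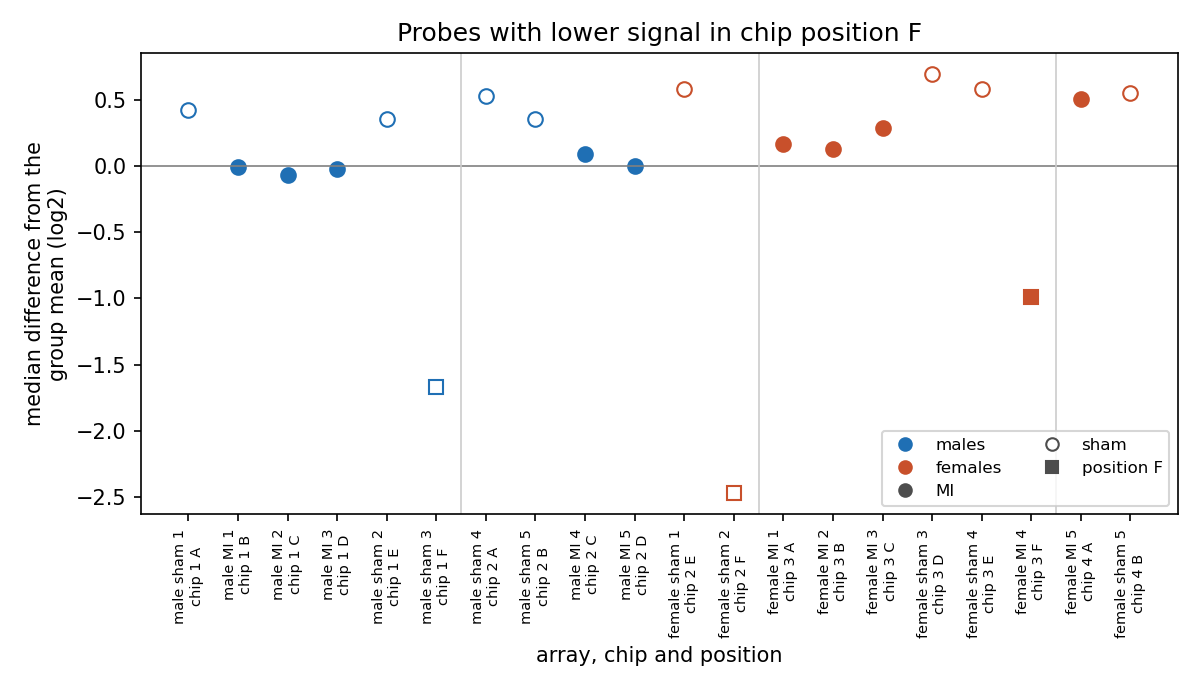
Median difference from the group mean (log2) on each of the 20 arrays, ordered by chip and position, over the 228 kept probes that lay more than 1.5 log2 units lower in position F. Male sham 3 (-1.67), female sham 2 (-2.47) and female MI 4 (-0.99), the 3 arrays in position F, lie below all others. The probes were chosen by their drop on these arrays, so that place is largely set by the choice. Over all kept probes, the differences from the group mean on each of them correlated with the mean of the other position F arrays (r = 0.591 to 0.631).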

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

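The tests of the RNA of these hearts, of single-probe loss in the last position of a chip, of position F for the counts of genes, and of the splits without the sex lists were chosen after the results had been seen. The other tests were chosen before theirs. Of 420 groups of 5 arrays tested for a far array, 43 passed the critical ratio of 0.71 (gap to the nearest array over the range of the group), or 10.2%. About 1 in 20 groups passes by chance. The far array was in position F in 18 of the 43, with 8 in male sham 3, 8 in female sham 2 and 2 in female MI 4, and female MI 3 followed with 6.

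For detected probes, male MI 4 lay low (ratio 0.738), and female sham 3 (0.719) and female MI 2 (0.914) lay high. The mean correlation within the group was lowest, and far from the others, in male sham 3 (0.747) and female sham 2 (0.736). In male sham 3 the values of Pln (0.93) and Eif2s3y (0.773) lay low, and those of Acads (0.794), Mcee (0.799), Thy1 (0.787), Tpm1 (0.796) and Urah (0.82) high. In female sham 2 the values of Pln (0.948), Col8a1 (0.852), Xist (0.818) and Retnla (0.711) lay low, and those of Kdm5d (0.737), Fhl1 (0.723) and Pcca (0.719) high. In female MI 4, Pln (0.842) and Xist (0.815) lay low.

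In female MI 3, Ndufa9 (0.887), Kcnv2 (0.804), Abcc9 (0.771), Mcee (0.764) and Ano10 (0.736) lay high, and Ccl5 (0.713) lay low. In female MI 5, Ankrd1 (0.746) and Kcnj8 (0.76) lay low. Among the male sham arrays, Mmgt2 lay low in male sham 1 (0.873) and Ciart low in male sham 2 (0.733). Col14a1 (0.752) and Fos (0.765) lay high in male sham 4, and Car3 (0.722), Ccl5 (0.757) and Cd74 (0.76) high in male sham 5. After MI in males, Ndufs8 lay low in male MI 2 (0.775), Tpm1 high in male MI 3 (0.738), Cxcl14 high (0.719) and Tnc low (0.743) in male MI 4, and Ccl12 (0.889), Ky (0.775) and Nppb (0.75) low in male MI 5.

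The first pattern weighed is the position of male sham 3, female sham 2 and female MI 4. In position F 577 kept probes lay more than 1 log2 unit lower, against 0 at the highest other position. If the RNA of these hearts held less of the transcripts, other probes of the same genes would fall too, and their median shift was -0.127, against -1.82 for the 228 dropped probes. With 75th percentile scaling the dropped probes shifted by -1.81, which argues against quantile normalisation as the cause. The shift of -0.127 in the other probes argues against a lower content of these transcripts in the 3 hearts. A loss of signal on single probes in the last position stays open, since the count of 577 against 0 probes is the pattern itself and cannot test it. The 3 arrays come from 3 groups, so the design gives no group to explain them.

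Female arrays called 4231 genes and male arrays 2373, a difference of 1858. Of 100 regroupings of the sexes, 21 gave a difference as large, the real grouping included, and the highest other was 3604, so chance is not excluded. Without the arrays in position F the ratio of the counts was 1.63, against 1.78 with them, which argues against those arrays as the whole cause. The counts with the chip as a block, given above, were also higher in females, but by a smaller margin. Within single chips, with unlike numbers of arrays, more genes were called in chip 1 males than in chip 3 females. Sex stays open as an untested explanation, and it cannot be told apart from the chip, because chip 1 is male and chips 3 and 4 are female.

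The test of the interaction passed camera at the preset correlation for 16 lists. Higher in females were interferon response (median 0.34), proteases and inhibitors (0.31), cell cycle (0.29), macrophage and monocyte (0.28), myofibroblast activation (0.27), fibrillar collagen and matrix (0.23), adhesion and leukocyte entry (0.22), ventricular stress (0.18), chemokines and cytokines (0.18) and ribosomal proteins (0.11). Lower were potassium and sodium channels (-0.34), branched chain amino acid breakdown (-0.33), citric acid cycle (-0.28), fatty acid oxidation (-0.26), adrenergic and renin-angiotensin signalling (-0.21) and oxidative phosphorylation (-0.0895, a direction that turned to 0.0845 with 75th percentile scaling). Of 100 shuffles of the arrays with the group means removed, 12 called as many lists, with a highest of 23 and a median of 7, so chance together with correlation between the genes of a list is not excluded. Without the arrays in position F 93.8% of the 16 lists (15) kept their call and direction, which argues against those arrays as the whole cause. Sex stays open as an untested explanation, and with an estimated correlation 0 lists passed.

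Other splits of the 10 arrays of each comparison were counted for 100 drawn from the 126 that exist, the real one included. In males 1 split gave as many genes as the real 2373, with a highest other of 6, and in females 1 gave as many as 4231, with a highest other of 3204, so chance can be excluded for both. That highest split exchanged female sham 2 and female MI 3. After sham surgery 4 splits gave at least the real 14 genes, with a highest other of 610, and after MI 3 splits gave at least the real 18, with a highest other of 970. Only the real split can fully separate sex-linked genes, so the same splits were counted again without the sex lists. After sham surgery 4 splits gave at least the real 5 genes, with a highest other of 607, and after MI 3 gave at least the real 11, with a highest other of 967. Few splits gave as many by these counts, yet some called many times the real number, which points to a structure of the samples. An unnamed probe outside the sex lists also differed strongly in both comparisons (log2 -2.46 and -2.64), so the real split kept an advantage. Chance is therefore not excluded for either comparison. The split with 610 set female sham 2 with male sham 1, 2, 3 and 5. That side takes all 3 sham arrays of chip 1 and 2 of chip 2. It also holds both sham arrays in position F, male sham 3 and female sham 2, so chip and position cannot be told apart there. The split with 970 set female MI 3 with male MI 1, 2, 4 and 5. With the chip as a block 7 and 4 genes remained in these comparisons. Array weights called 1981 genes between the sexes after MI, and 5 of 100 splits gave as many, with a highest other of 2765, so chance is not excluded. For the interaction the count of 0 genes decides nothing, since 100 of 100 regroupings give as many by construction, and the highest other was 2.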

How the results depend on the processing

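Leaving out the position F arrays and a term for that position were chosen after the data had been seen. Over named genes 6053 of 6243 values under other settings kept direction and side of the threshold, 160 lost and 30 gained a call, and over lists 1997 of 2174 did, with 160 lost and 16 gained. The adipocyte median after sham surgery reversed, to -0.0835, with a filter for detection on all 20 arrays. With 75th percentile scaling the medians of 2 other called lists changed sign, ribosomal proteins in males (to -0.157) and oxidative phosphorylation in the interaction (to 0.0845), as did those of some uncalled lists. Of 49 lists fry called 21 in males and 35 in females. Between the sexes it called 2 after sham surgery and 7 after MI, and 0 for the interaction. Camera called 21, 23, 9, 21 and 16 at the preset correlation, and 0, 0, 2, 2 and 0 with an estimated one. Array weights called 4150 genes in males, 32 between the sexes after sham surgery, 1981 after MI and 31 for the interaction. A 2-fold threshold left 308, 641, 7 and 6 genes in males, in females, between the sexes after sham surgery and after MI, and fits within 1 chip, with fewer arrays, 624 in males (chip 2), 946 in females (chip 3) and 1 between the sexes (chip 2). Between the sexes after sham surgery and after MI, a filter for detection on all 20 arrays left 6 and 9, the chip as a block 7 and 4, and omitting the sex lists 5 and 11. After sham surgery a fit to only the 2 groups gave 7 and the term for position F 39. With 1 array left out the counts were 1711 to 2711 in males, 3501 to 4634 in females, 9 to 45 after sham surgery, 11 to 635 after MI and 0 for the interaction. The causes of these moves were not tested. With the replicate number as a block the counts were 2177, 4117, 15, 15 and 0. These numbers only follow the order of the arrays and are not read as pairing. Of 20 arrays 4 correlated best with their own number, and r over 30 pairs was -0.423 to 0.472. Background intensity limits genes below the detection threshold, for which only a lowest fold is given.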

Other observations

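Every result in this part comes from lists fixed in advance, and which to print was chosen after the values were seen. Genes of leukocyte adhesion and entry rose after MI, 12 of 18 in males and 15 in females, and 13 and 17 when adjusted over the list alone (medians 0.66 and 0.79, camera adjusted p = 7.98e-08 and 2.39e-08, adjusted p = 0.134 and 0.123 with an estimated correlation). Of 22 acute phase and complement genes 7 rose in males and 9 in females, and 11 and 10 when adjusted over the list alone (medians 0.35 and 0.42, camera adjusted p = 0.000146 and 0.00177, adjusted p = 0.244 and 0.248 with an estimated correlation). Of 23 genes of the unfolded protein response 4 rose in males and 7 in females, and 4 and 8 when adjusted over the list alone (medians 0.28 and 0.22, camera adjusted p = 0.0166 and 0.0182, adjusted p = 0.288 and 0.237 with an estimated correlation). With 75th percentile scaling these medians were 0.115 and 0.16, and those of acute phase and complement 0.18 and 0.38. Of 33 ribosomal protein genes 11 rose in females (median 0.24, camera adjusted p = 4.08e-05, adjusted p = 0.211 with an estimated correlation) and 3 in males, where the median of 0.11 turned to -0.16 with 75th percentile scaling. Of 13 circadian clock genes 2 fell in males and 4 in females (medians -0.19 and -0.46), and the list was not called (camera adjusted p = 0.144 and 0.0954).

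Between the sexes after sham surgery 5 more lists passed camera with few or no called members. In all 9 lists passed there at the preset correlation, the sex lists included. The shuffles described above called a median of 7 lists with the group means removed. They were run only for the interaction, so chance is not excluded for these lists or for the immediate early and adipocyte lists. Fibroblast genes had a median of 0.15 with 1 of 16 called (camera adjusted p = 0.0185, adjusted p = 0.316 with an estimated correlation), matrix genes 0.14 with 2 of 33 (0.0192 and 0.84) and cell cycle genes 0.16 with 0 of 34 (0.0226 and 0.84). Atrial and conduction genes had a median of 0.35 and antigen presentation genes -0.22, with 0 called in either (camera adjusted p = 0.0479 for both, and 0.728 and 0.84 with an estimated correlation), and leaving out any of 11 and 9 arrays singly, or 11 and 12 of the other settings, ended these calls. The fibroblast and matrix lists had an adjusted p of 0.598 and 0.354 with the chip as a block, and medians of 0.072 and 0.0558 with 75th percentile scaling. Leaving out singly any of 3 and 4 arrays ended their calls. The highest adjusted p was 0.0874 without female sham 4 for fibroblast genes and 0.148 without female sham 3 for matrix genes. After MI immediate early genes were higher in females (median 0.33, camera adjusted p = 0.00134, adjusted p = 0.326 with an estimated correlation), which ended without female MI 3 (0.0892) and with the chip as a block (0.509).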
